A study of Zea mays with 54 samples.

How the data were processed

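Bulk RNA-seq of maize ear and tassel meristems, of SK1 and TS1 mutants with their wild types and of FM-S3 protoplasts, and single-cell RNA-seq of florets, were analysed from the deposited tables. The authors deposited raw counts per gene for the bulk libraries and raw UMI counts per gene and cell for the single cells: the values were whole numbers whose totals differed between libraries. Per the submitters' processing notes, the tools were Trimmomatic, fastp, HISAT2, STAR, featureCounts 1.6.3 and deepTools 3.3.0 and the genome build was B73 RefGen_v4; their roles and order, and the strand setting of the counting, are not given in the sources used here. The single-cell libraries were made with a BD Rhapsody whole transcriptome kit, per the labels' protocols, and how cells were filtered is not given there.

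The stage table held 31 columns. Of these, 29 were matched to samples by name and 2 that share 1 name were not used, which left Tassel FM-S1 with replicates 1 and 3 and Tassel FM-S2 with 1 library. That library has no replicate of its own; the fit over all 12 groups assumes that it varies like the others. Each bulk table had 44474 rows: 44146 with Zm00001d IDs, 174 with GRMZM5G IDs and 154 microRNA genes. No row without a gene name was present. Gene names were sought in the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, which paired 153 of the 154 microRNA rows and 0 of the other IDs. As a result, none of the 17 lists of genes or markers fixed before the data were examined had a member paired with an ID, and their tests were not run.

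The rule for named genes, fixed before the data were examined, took the targeted gene first, then list members, then up to 5 named genes per direction with the largest change among called genes with a mean log2 CPM of at least 2 and separated libraries, and otherwise at most 2 IDs per direction. With names for microRNA genes alone, its size criterion would have left MIR159a, MIR160d, MIR167d and MIR394b. Describing the microRNA rows by family, called or not, was chosen after the data were seen. Roles of microRNA families given in the text are background knowledge.

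Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM scaling, estimateDisp, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment over the tested genes of each comparison and a threshold of 0.05. The 29 stage libraries were fitted together with 1 mean per group, giving 17 residual degrees of freedom. The SK1 (5 libraries) and TS1 (6) tables were fitted on their own, and the protoplast comparison on 8 libraries with inflorescence as a covariate, joining raw counts of both tables by gene ID. In all, 20 comparisons of this kind were made. Common biological coefficients of variation were 0.1274 for the stages, 0.04801 for SK1, 0.1136 for TS1 and 0.1516 for protoplasts. SEs of log2 fold changes were taken from the log2 fold change and its F statistic and are approximate. CPM values use TMM-scaled library sizes. A group with 0 counts was given a floor of 3 counts over the group, and folds against it are lower bounds that cover counting error only. Sets were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Overlaps of calls are set beside the number expected of independent lists. Expression along an ear-to-tassel axis used 989 genes higher in the tassel and 735 higher in the ear at FM-S1, FM-S2 and FM-S3.

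The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Counts were drawn from the real means, pooled over the compared groups so that the other genes did not differ. The changed genes were taken from those with a mean log2 CPM of at least 2. Recovery was therefore not measured for low-count rows such as most microRNA genes. At adjusted p under 0.05 the 2-fold changes recovered were 82% in the simulated IM comparison, 69% for FM-S2, 80% for FM-S3, 100% for SK1, 92% for TS1 and 91% for protoplasts; of the 4-fold changes, 96% or more were recovered in each.

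Replicates of a group were compared by a chi-square test of their counts. The closest pair, SK1 Mutant replicates 1 and 2, had a chi-square per gene of 1.208 (p = 3.1e-89 over 20907 genes), so no pair was counted as 1 sample. Over so many genes a small difference between libraries gives a very low p-value. The test therefore cannot show that replicates are separate samples. Each library of a group of 3 was also compared with the best mixture of the other 2. The lowest chi-squares per gene were 1.183 for TS1 WT replicate 3, 1.195 and 1.254 for SK1 Mutant replicates 1 and 2, 1.495 for Tassel IM replicate 3 and 1.534 for TS1 Mutant replicate 3. Whether equal replicate numbers pair samples was checked by correlating deviations from group means. With Ear SPM and Ear SM all 3 pairs lay above 0.1 (0.118 to 0.309), so these numbers may pair the samples; in the other 16 comparisons checked at least 1 pair did not. The source of that pairing is not given in the labels.

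Alternatives fixed beforehand were DESeq2 size factors, DESeq2 1.42.0's Wald test, no filter on low counts, a fold threshold, a replicate block, the compared groups alone in the fit, each inflorescence alone for protoplasts, leaving out each library in turn, and other stages or gene sets for the relation of mutant and sex differences. Added after seeing the data were counts thinned to the shallowest library, TS1 without the third replicates, and TS1 without a stretch of table rows. The single-cell columns name 8 sets that were not matched to samples, so the planned single-cell comparisons, clustering and class shares were not run; per-set values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.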

Results

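RNA was sequenced from developing inflorescences of maize, which bears male flowers in the tassel and female flowers in the ear. Bulk libraries covered 6 meristem stages in each inflorescence: inflorescence meristem (IM), spikelet pair meristem (SPM), spikelet meristem (SM) and floral meristem at stages FM-S1, FM-S2 and FM-S3. The 29 libraries analysed comprised 3 per inflorescence at IM, SPM and SM, 2 at FM-S1, 2 at FM-S3, and at FM-S2 2 from the ear and 1 from the tassel. Their totals (M, mega-counts) ran from 16.52 to 73.04 M counts in the ear, the highest being Ear SPM replicate 3. In the tassel they ran from 9.117 to 13.98 M counts at IM to FM-S1 and from 21.33 to 33.48 M at FM-S2 and FM-S3. Further bulk libraries came from SK1 mutants (3) and their wild type (2), from TS1 mutants (3) and their wild type (3), and from FM-S3 protoplasts of ear (2) and tassel (2). These held 10.88 to 12.55, 8.249 to 15.75 and 15.72 to 18.89 M counts respectively. A single-cell matrix held 53900 cells in 8 sets with 601740524 UMIs. The gene IDs of the deposited tables were paired with names for microRNA genes alone, so the genes named in each comparison are microRNA genes, with at most 2 IDs in each direction. A microRNA gene row counts reads over an annotated precursor locus, not the mature microRNA. Values are CPM, mean ± SD over n libraries. Log2 fold changes are given with their standard error (SE). No label says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

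The comparison of tassel and ear at each stage asks where the male and the female inflorescence differ. MIR529, whose microRNA is known in grasses to target SQUAMOSA promoter-binding-like transcription factor genes, was read in the tassel and scarcely in the ear. Its row held 0 counts in the ear from IM to FM-S2 and 3 counts in the FM-S3 ear libraries. In the tassel it stood at 1.08 ± 0.375 CPM at SM (n = 3), 10.1 ± 0.474 at FM-S1 (n = 2), 3.88 in the FM-S2 library and 6.32 ± 1.6 at FM-S3 (n = 2). Against a floor of 3 counts over the ear group, MIR529 was at least 21.8-fold higher in the tassel at SM, 161-fold at FM-S1 and 79.8-fold at FM-S2 (edgeR's quasi-likelihood test, adjusted p = 1.58e-05, 1.47e-07 and 1.46e-06). At FM-S3 the call stood on 291 tassel counts against 3 ear counts (edgeR, adjusted p = 3.5e-07).

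MIR156j, whose microRNA targets the same class of transcription factor genes, ran the other way and peaked at SM. It stood at 16.8 ± 1.41 CPM in the ear and 5.07 ± 3.24 in the tassel at SM (n = 3 each), a log2 fold change of -1.70 (SE 0.36; edgeR, adjusted p = 0.000757). It was also lower in the tassel at SPM by a log2 fold change of -3.54 and at FM-S1 by -1.89. The FM-S1 call was lost without Tassel FM-S1 replicate 3. The other miR156 row tested, MIR156d, was higher in the tassel at FM-S3. It held 35 tassel counts against 0 ear counts, at least a 13.3-fold difference (edgeR, adjusted p = 0.00527). MIR167d, of a family that targets auxin response factor genes, was higher in the tassel at IM, SPM, SM and FM-S1, with log2 fold changes of 0.88, 0.94, 2.11 and 2.68. The IM call of MIR167d was lost with the compared groups alone in the fit. At FM-S1 it stood at 8.66 ± 1.17 CPM in the tassel and 1.34 ± 0.0712 in the ear (n = 2 each), a 6.43-fold difference (SE of the log2 value 0.33; edgeR, adjusted p = 1.66e-06). At FM-S2 and FM-S3 its log2 fold changes were -0.62 and -0.50 and passed no threshold. At both of these stages 1 other of the 4 miR167 rows was called lower in the tassel. MIR159a, whose microRNA targets GAMYB-type transcription factor genes, was higher in the tassel at IM, SPM, SM, FM-S1 and FM-S3, by 0.84, 1.73, 0.74, 1.75 and 0.85 on the log2 scale. At FM-S2 its log2 fold change was -0.46 and passed no threshold, while the other miR159 row was called lower in the tassel. The SM call of MIR159a was lost without Ear SM replicate 2, without Ear SM replicate 3 and with the compared groups alone in the fit. MIR398b stood at 4.72 ± 3.18 CPM in the IM tassel (n = 3), where the ear held 3 counts, and was higher in the tassel at FM-S3 by a log2 fold change of 4.65 (SE 0.73; edgeR, adjusted p = 5.41e-05). MIR172e, which is the tasselseed4 locus and acts on spikelet meristem fate through APETALA2-like genes, peaked at SPM with 1.85 ± 0.866 CPM in the ear and 1.59 ± 0.387 in the tassel (n = 3 each). No stage gave a tassel-to-ear call for MIR172e, and its FM-S1 to FM-S3 values rest on 10 counts or fewer per group.

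Members of the miR171 family moved in opposite directions at FM-S3. MIR171f (199 tassel counts) and MIR171j (31 tassel counts) had 0 ear counts, and were at least 77.3-fold and 12-fold higher in the tassel (edgeR, adjusted p = 0.000102 and 0.000214). MIR171f was not called by the DESeq2 alternative. MIR171c went the other way, with 98 ear counts against 2 tassel counts. MIR166a and MIR166c were both lower in the tassel, MIR166a with a log2 fold change of -1.55 (SE 0.51; edgeR, adjusted p = 0.0165). MIR169c and MIR168a were higher in the tassel by 2.71 and 2.64 on the log2 scale, and MIR160c, MIR319a and MIR2118c lower by -1.71, -1.91 and -2.31. The MIR319a call was lost when counts were thinned to the shallowest library. Copies of a family are near-identical over part of the locus, so reads may be split between them.

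**Figure D1:**
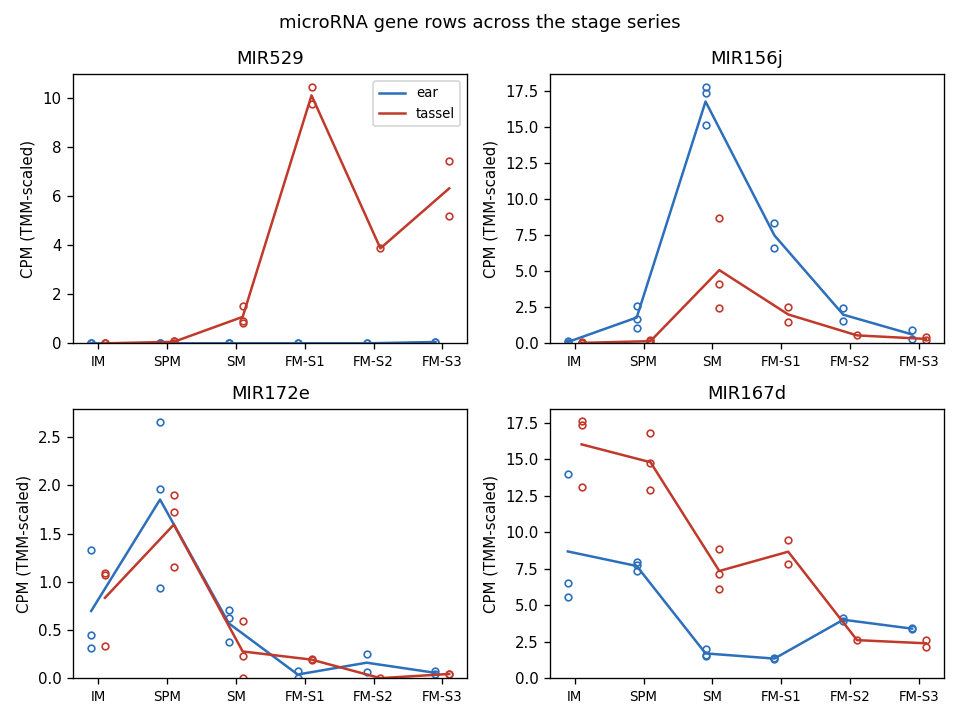
TMM-scaled CPM of 4 microRNA gene rows (linear axes from 0) at each of the 6 stages in ear and tassel; open points are libraries and lines join group means. MIR529 rises in the tassel from SM and stays near 0 in the ear, MIR156j peaks at SM with the higher level in the ear, MIR172e peaks at SPM in both, and MIR167d is higher in the tassel up to FM-S1.

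Over all 24798 tested genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called 3859 genes higher and 4031 lower in the tassel at IM. At SPM the numbers were 4988 and 4746, at SM 4451 and 4950, at FM-S1 4059 and 4441, at FM-S2 3480 and 2207, and at FM-S3 5516 and 4909. With a 2-fold change required as well, FM-S3 gave 3333 higher and 1253 lower genes. Of the 44 microRNA rows tested, 6 were higher and 2 lower at IM, 10 and 4 at SPM, 5 and 3 at SM, 10 and 3 at FM-S1, 4 and 10 at FM-S2, and 9 and 8 at FM-S3. Zm00001d038965 was lower in the tassel from SM to FM-S3; at SM it stood at 28.9 ± 4.46 CPM in the ear and 0.0695 ± 0.0614 in the tassel (n = 3 each). Zm00001d031971 stood at 251.5 ± 51.6 CPM in the FM-S3 tassel and 0.0936 ± 0.032 in the ear (n = 2 each; edgeR, adjusted p = 1.84e-11). The FM-S1 count fell from 8500 to 5641 without Tassel FM-S1 replicate 3. The FM-S2 count fell from 5687 to 3619 without Ear FM-S2 replicate 1 and to 3644 without Ear FM-S2 replicate 2, and rests on a tassel group of 1 library that is assumed to vary like the other groups. With the compared groups alone in the fit, tassel versus ear, IM gave 4150 calls and tassel versus ear, FM-S2 gave 12564.

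A few genes kept their direction throughout. In all, 217 genes were higher in the tassel at all 6 stages and 368 higher in the ear, where independent lists of these sizes would share 0.712 and 0.486 genes. A call at 1 stage or more was made for 19661 genes, and 2934 of these were called in opposite directions at different stages.

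**Figure D2:**
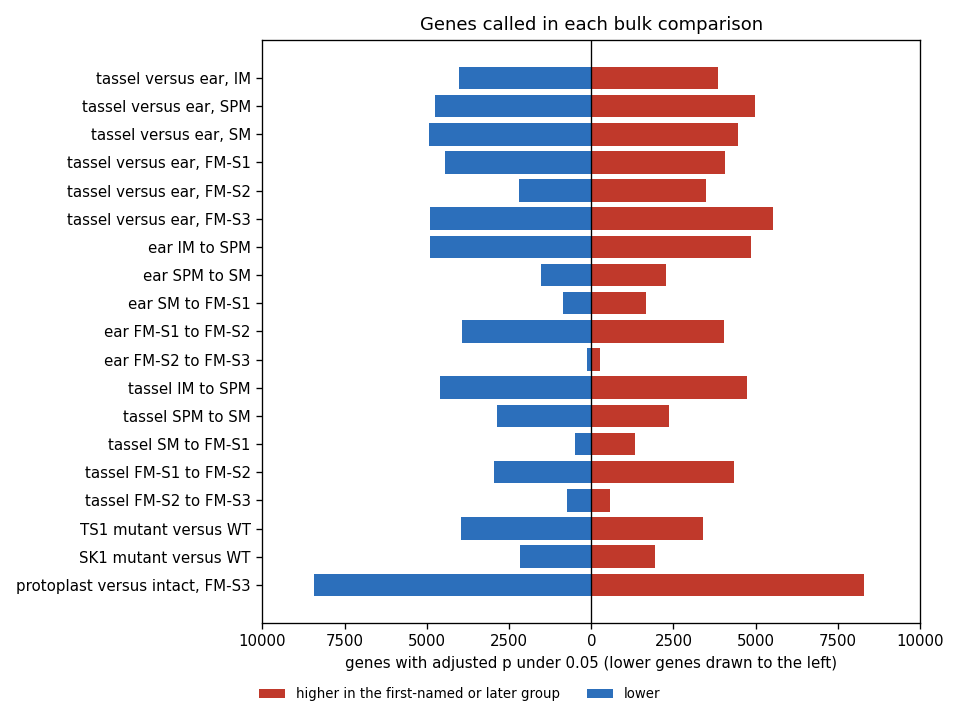
Number of genes called by edgeR's quasi-likelihood test (adjusted p under 0.05) in each bulk comparison; bars to the right count genes higher in the first-named or later group and bars to the left genes lower in it. The bars for protoplasts are the longest, with 8302 higher and 8440 lower genes, and those for FM-S2 to FM-S3 in the ear the shortest, with 276 and 143.

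The comparison of successive stages asks how each inflorescence changes as its meristems progress. MIR394b fell from IM to SPM in both inflorescences, from 8.19 ± 0.882 to 0.51 ± 0.172 CPM in the ear and from 6.97 ± 0.389 to 0.876 ± 0.545 in the tassel (n = 3 each). These were log2 fold changes of -3.87 (SE 0.29) and -2.96 (SE 0.32) with edgeR adjusted p = 6.46e-10 and 1.95e-07. MIR319c, of a family that targets TCP transcription factor genes, fell in the ear over the same step from 4.10 ± 1.91 to 0.0814 ± 0.0458 CPM (n = 3 each). In the tassel MIR319c fell from SPM to SM by at least 18.7-fold and MIR398b by at least 15.5-fold, both to 0 counts (edgeR, adjusted p = 0.000467 and 0.000302). MIR156j rose in the ear from IM to SPM by 4.28 on the log2 scale and from SPM to SM by 3.21. In the tassel MIR156j rose from SPM to SM by 5.05 (SE 0.65; edgeR, adjusted p = 5.71e-06). MIR172e rose in the ear from IM to SPM by a log2 fold change of 1.43 (SE 0.50; edgeR, adjusted p = 0.0266), then fell by 1.75 to SM; the tassel value fell by 2.53 from SPM to SM. The IM to SPM call of MIR172e was lost in 5 of 12 alternatives and its SPM to SM call in the ear in 4 of 12. Its SPM to SM call in the tassel was lost without Tassel SM replicate 2 and without Tassel SM replicate 3.

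From FM-S1 to FM-S2, 14 of the 44 microRNA rows rose and 1 fell in the ear, and 3 rose and 5 fell in the tassel; the difference between the inflorescences over this step was not tested. The 3 rising in the tassel, MIR160c, MIR164b and MIR162, lost their calls with DESeq2's Wald test, without Tassel FM-S1 replicate 1 and without Tassel FM-S1 replicate 3. MIR159a rose in the ear from 6.67 ± 0.621 to 21.9 ± 0.21 CPM (n = 2 each), a 3.29-fold change (SE of the log2 value 0.28; edgeR, adjusted p = 6.79e-05). MIR167d rose 2.97-fold in the ear and had a log2 fold change of -1.73 (SE 0.38; edgeR, adjusted p = 0.00162) in the tassel. The rows as a set were called upward over that step in the ear by camera with its preset correlation (adjusted p = 0.00114), and with an estimated correlation the adjusted p = 0.206. From FM-S2 to FM-S3 the tassel had 5 rows rising and 0 falling, among them MIR159a with a log2 fold change of 1.49 (SE 0.33; edgeR, adjusted p = 0.0102). With the compared groups alone in the fit no gene, and so none of these 5, was called by edgeR. That set was also called upward with the preset correlation (adjusted p = 6.13e-07), with adjusted p = 0.0713 when the correlation was estimated. None of the 20 comparisons kept a call for the microRNA set with an estimated correlation.

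Over all genes, in the ear, 4847 genes rose and 4895 fell from IM to SPM, 2283 and 1541 from SPM to SM, 1658 and 853 from SM to FM-S1, 4028 and 3940 from FM-S1 to FM-S2, and 276 and 143 from FM-S2 to FM-S3. In the tassel the numbers were 4734 and 4600, 2365 and 2860, 1323 and 509, 4342 and 2960, and 580 and 725. Zm00001d022193 rose from IM to SPM in the ear from 0.674 ± 0.264 to 189 ± 14.8 CPM and in the tassel from 0.811 ± 0.5 to 112.4 ± 40.2 (n = 3 each). Zm00001d041781 rose in the ear from 0.0852 ± 0.0144 CPM at FM-S1 to 9.42 ± 0.497 at FM-S2 and 52.7 ± 1.89 at FM-S3 (n = 2 each). Across genes, which are not independent replicates, the ear and tassel changes of the same step correlated with r = 0.6055 for IM to SPM, 0.4993 for SPM to SM, 0.2817 for SM to FM-S1, 0.01143 for FM-S1 to FM-S2 and 0.2482 for FM-S2 to FM-S3. Of genes called in both inflorescences, 98.26%, 95.32%, 90.38%, 67.93% and 96.32% had the same direction at these steps. Several of these counts turned on 1 library. The comparison ear SM to FM-S1 gave 1232 calls without Ear FM-S1 replicate 1 and 1512 without Ear FM-S1 replicate 2, and tassel SM to FM-S1 gave 840 without Tassel FM-S1 replicate 1 and 927 without Tassel FM-S1 replicate 3. FM-S1 to FM-S2 gave 4695 calls in the ear without Ear FM-S2 replicate 1, and in the tassel 4678 without Tassel FM-S1 replicate 1 and 4655 without Tassel FM-S1 replicate 3. FM-S2 to FM-S3 in the ear gave 74 calls without Ear FM-S2 replicate 1, 82 without Ear FM-S2 replicate 2, 80 without Ear FM-S3 replicate 1 and 101 without Ear FM-S3 replicate 2. With the compared groups alone in the fit, ear IM to SPM gave 5278 calls, ear SPM to SM 2416, ear SM to FM-S1 1298, ear FM-S2 to FM-S3 6741, tassel SM to FM-S1 4425, tassel FM-S1 to FM-S2 12250 and tassel FM-S2 to FM-S3 0. For that 0, from edgeR with 1 library against 2, 3668 genes had unadjusted p under 0.05, and DESeq2's Wald test on all groups called 1462.

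A direct test asked whether the change from FM-S1 to FM-S3 differed between tassel and ear. The tassel libraries held 10.36 and 10.92 M counts at FM-S1 and 21.33 and 23.25 M at FM-S3. A batch shared by the early tassel libraries was not separated from biology and would enter this difference. MIR167d had a log2 difference of -3.19 (SE 0.46; edgeR, adjusted p = 2.07e-05), the tassel change lying below the ear change, and its relatives MIR167a and MIR167g had -4.09 and -3.78. MIR319a, MIR166a and MIR164d were also lower in the tassel by this measure, with -3.71, -2.65 and -2.46. The MIR319a call was lost without Tassel FM-S1 replicate 3. Of the 44 microRNA rows, 1 lay higher in the tassel and 7 lower. The 1 higher, MIR171j, rests on groups with 0 counts and was not called with DESeq2's Wald test or without Ear FM-S1 replicate 2. Over all genes, 3755 had a higher and 2984 a lower change in the tassel, a share of 55.72% higher that became 63.05% with DESeq2 size factors.

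The SK1 comparison asks what loss of this gene changes at the early floret stage. SK1 is known in maize for protecting the pistils of the ear from elimination. The targeted gene was not analysed here, because the sources used do not pair its name with an ID. MIR159a rose in the mutant from 21.2 ± 1.86 (n = 2) to 29.2 ± 2.82 CPM (n = 3), a 1.38-fold change (SE of the log2 value 0.10; edgeR, adjusted p = 0.003). MIR171d fell from 2.72 ± 0.864 to 1.03 ± 0.0721 CPM, a log2 fold change of -1.38 (SE 0.31; edgeR, adjusted p = 0.00336); this call was lost without SK1 WT replicate 1. MIR162 fell from 3.86 ± 0.749 to 2.34 ± 0.45 CPM (edgeR, adjusted p = 0.0373), a call lost with DESeq2's Wald test and without SK1 WT replicate 2, SK1 Mutant replicate 1 or SK1 Mutant replicate 2. MIR172e stood at 2.71 ± 0.355 CPM in the wild type and 3.14 ± 0.295 in the mutant (log2 fold change 0.22, SE 0.23; edgeR, adjusted p = 0.56). Zm00001d022630, which in the FM-S1 tassel stood at 140.7 ± 8.81 CPM against 1 count in the ear, rose in the mutant from 0.497 ± 0.082 to 9.57 ± 0.605 CPM (log2 fold change 4.24, SE 0.27; edgeR, adjusted p = 8.42e-10). Zm00001d041781, which rose along the ear stages, fell in the mutant from 19.1 ± 0.577 to 0.298 ± 0.127 CPM (log2 fold change -5.95, SE 0.24; edgeR, adjusted p = 6.94e-13).

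For SK1 mutant versus WT, 1936 of 21100 tested genes were higher and 2158 lower in the mutant, and 404 changed by 2-fold or more. The count of 4094 fell to 2376 without SK1 Mutant replicate 1, to 2669 without SK1 Mutant replicate 2 and to 2088 with DESeq2's Wald test. Mutant replicates 1 and 2 differed by little more than sampling noise (chi-square per gene 1.208, where 1 is sampling noise). Whether they are separate samples was not shown. Mutant changes correlated across 20986 genes with the FM-S3 tassel-over-ear differences with r = 0.2854 and rho = 0.1406. Called genes shared a direction more than independent lists would: 684 were higher in both (expected 390.2) and 611 lower in both (473.6), against 240 (423) and 443 (436.8) with opposite directions. Genes higher in the FM-S3 tassel rose as a set with camera's preset correlation (p = 0.00702) and genes higher in the ear fell (p = 0.00428). With an estimated correlation neither call held, with p = 0.282 and p = 0.298.

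The TS1 comparison asks the same of a tasselseed gene, a lipoxygenase of jasmonate synthesis needed for pistil elimination in the tassel. The sample titles name the ear as the source, while the series description speaks of tassel or ear for the mutants. The targeted gene was again not analysed here, for the same reason. MIR160d fell in the mutant from 7.24 ± 0.323 to 3.05 ± 0.575 CPM (n = 3 each), a log2 fold change of -1.22 (SE 0.18; edgeR, adjusted p = 0.00139). MIR159a fell from 14.1 ± 0.829 to 7.43 ± 1.03 CPM, a log2 fold change of -0.91 (SE 0.13; edgeR, adjusted p = 0.00115). MIR529, high in the tassel of the stage series, held 56 counts in the wild type (1.36 ± 0.659 CPM) and 2 in the mutant (0.0609 ± 0.06 CPM; edgeR, adjusted p = 0.00319). The other 5 of the 8 microRNA rows tested passed no threshold, MIR167d with 1.25 ± 0.381 CPM in the mutant and 1.27 ± 0.466 in the wild type among them. All 3 called rows lost their call when replicate 3 of both groups was left out. Zm00001d003267 rose from 2 counts in the wild type to 205 ± 12.7 CPM in the mutant, and Zm00001d007405 fell from 43.9 ± 3.12 CPM to 0 counts (n = 3 each).

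For TS1 mutant versus WT, 3387 of 22499 tested genes were higher and 3951 lower in the mutant, and 1382 of the 2001 changes of 2-fold or more were decreases. The count of 7338 depends on the third replicates: it was 4242 without TS1 WT replicate 3, 4338 without TS1 Mutant replicate 3 and 1087 without either. In both groups the counts of replicate 3 lay close to a mixture of replicates 1 and 2. The chi-square per gene was 1.183 in the wild type and 1.534 in the mutant, where 1 is sampling noise. The weight of replicate 1 in the mixture was 0.503 and 0.541. Replicates 1 and 2 differed from each other with 11.37 and 7.432. Whether replicate 3 is a separate sample was not shown, and the TS1 p-values and n = 3 count it as one.

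Genes that separate tassel from ear differed between TS1 mutant and wild type in the direction of the ear. An earlier stage of the mutant libraries was not separated from this. Across genes the TS1 change also correlated with the tassel change from FM-S1 to FM-S3 (r = -0.3397). Of the genes called in both comparisons at FM-S3, 1981 were lower in the mutant and higher in the tassel (802.9 expected of independent lists) and 1517 higher in the mutant and higher in the ear (699.9), while 216 (707.2) and 166 (794.6) went the other way. Across 21577 genes the mutant change correlated with the FM-S3 tassel-over-ear difference with r = -0.5677 and rho = -0.437, and with r = -0.2516 at FM-S1. By camera the tassel-higher genes fell as a set (p = 1.76e-20 with the preset correlation, p = 0.00501 with an estimated one) and the ear-higher genes rose (p = 2.23e-15 and p = 0.0023). The SK1 and TS1 changes correlated with r = -0.3187 across 20573 genes. The mutant and stage tables share no libraries.

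**Figure D3:**
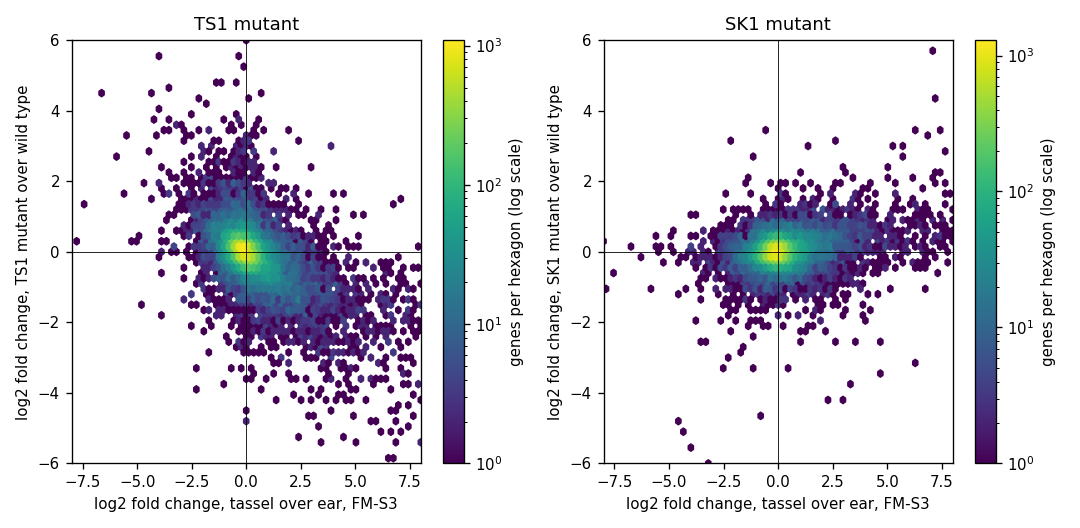
Log2 fold change, mutant over wild type (vertical), against log2 fold change, tassel over ear at FM-S3 (horizontal), per gene, for TS1 and SK1; genes beyond the drawn axes are not shown. The TS1 cloud slopes downward (r = -0.5677) and the SK1 cloud slightly upward (r = 0.2854).

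**Figure D4:**
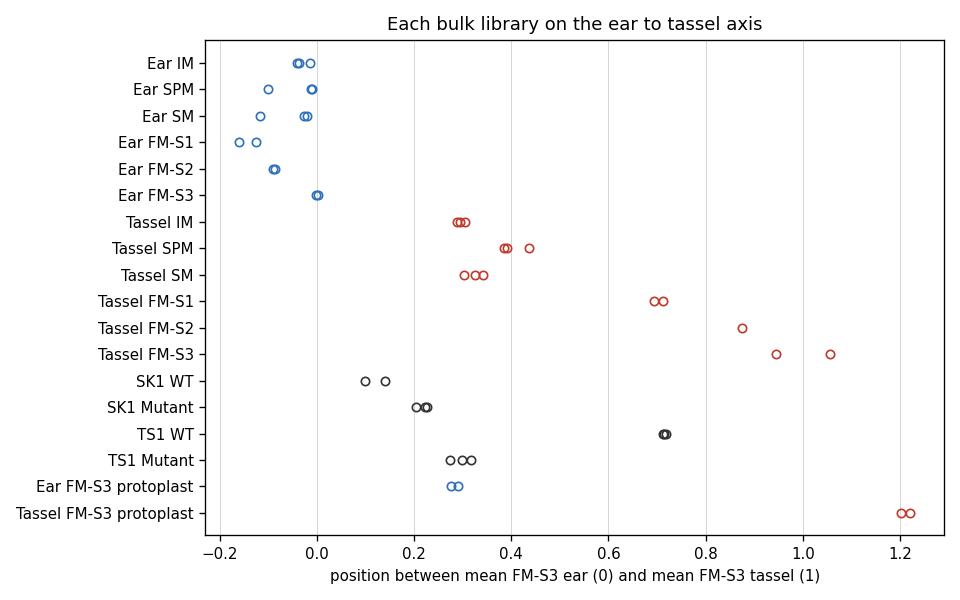
Position of each bulk library on the axis from the FM-S3 ear mean (0) to the FM-S3 tassel mean (1). The TS1 wild-type libraries lie nearer 1 than the TS1 mutant libraries.

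The protoplast comparison measures what enzymatic release of cells, the step before single-cell capture, does to FM-S3 expression. Most microRNA rows fell: 24 of the 34 tested were lower in protoplasts, 7 higher and 3 uncalled. MIR159a fell from 23.5 ± 0.171 to 8.55 ± 0.0864 CPM in the ear and from 42.8 ± 0.791 to 4.92 ± 0.766 in the tassel (n = 2 each), a joint log2 fold change of -2.24 (SE 0.32; edgeR, adjusted p = 0.000541). MIR167d fell by 4.75 on the log2 scale (SE 0.45; edgeR, adjusted p = 3.17e-05) and MIR160c by 2.54. MIR529 fell in the tassel libraries from 6.06 ± 1.65 to 1.20 ± 0.353 CPM (n = 2 each). MIR1432 and MIR399j, the latter of a family induced by phosphate starvation, held 0 counts in the intact libraries and 175 and 32 counts in protoplasts (edgeR, adjusted p = 4.88e-05 and 0.000754). By camera the microRNA set had adjusted p = 0.0121 with the preset correlation and 0.189 with an estimated one.

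Of 24554 genes, 8302 were higher and 8440 lower in protoplasts (49.59% higher, 52.1% with DESeq2 size factors). Changes of 2-fold or more were 5263 increases and 1403 decreases. Zm00001d006947 rose from 0.149 ± 0.136 to 524.3 ± 330 CPM and Zm00001d017180 fell from 18.8 ± 7.67 to 0.867 ± 0.684 (4 libraries of both inflorescences each). Genes at least 2-fold higher in protoplasts took 5.98% to 9.47% of counts in the 4 intact libraries and 26.2% to 39.6% in the 4 protoplast libraries, shares computed on the libraries that defined the genes. Protoplast and intact libraries stand in separate tables, so treatment and any difference in library preparation cannot be told apart.

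The single-cell matrix is described without comparing groups, because its 8 sets of cells were not tied to samples here. It held 30782 genes and 53900 cells, with a median of 9443 UMIs and 4203 genes per cell and at least 2822 UMIs in every cell. Genes 2-fold higher in bulk protoplasts took 23.73% to 39.25% of the UMIs of a set. Summed over cells, the sets correlated with each other with r from 0.9471 to 0.9993 across genes. All 52 microRNA rows of the matrix had a UMI, led by MIR169e with 602, MIR160d with 366 and MIR2118c with 350. MIR529 had 197 UMIs, and at most 1.02% of the cells of a set held one.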

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

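Of the tests in this part, those of a stage before FM-S1, of chance placement along the table and of a mutant or a wild-type segment, the thinning of counts, and the window and 4-fold size of the placement test were chosen after the results were seen. The change from FM-S1 to FM-S3 differed between tassel and ear in 6739 genes by a direct test of the difference (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The batch of early tassel libraries weighed below would enter this difference and was not separated from it. Among microRNA genes the log2 difference was -3.19 for MIR167d, -4.09 for MIR167a, -3.78 for MIR167g, -3.71 for MIR319a, -2.46 for MIR164d, -2.65 for MIR166a and -3.52 for MIR166c, and 9.8 for MIR171j. The MIR171j value is a fitted one that rests on 0 counts in the ear at FM-S3 and in the tassel at FM-S1, so it measures no size of change; the FM-S3 difference was at least 12-fold, and the call was lost with DESeq2's Wald test and without Ear FM-S1 replicate 2. The protoplast difference at FM-S3 also differed between the inflorescences, in 5161 genes by the same kind of test. Signals were present in data that no comparison used. The microRNA rows of the single-cell matrix held 3316 UMIs, and the columns sharing a name held 11839980 and 29981782 counts.

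In the TS1 comparison, mutant libraries lay further from the tassel profile than wild-type libraries: on an axis from the FM-S3 ear at 0 to the FM-S3 tassel at 1, the mean position was 0.715 for the wild type and 0.297 for the mutants (n = 3 each; exact p = 0.1, the smallest possible). The wild-type position was above the 0.6 set beforehand for libraries that hold tassel tissue, so a tassel origin is consistent with it, although the titles name the ear. Leaving out the stretch of table rows weighed next gave r = -0.5833, so that stretch does not carry the relation. An earlier stage of the mutants stays open: their position is near tassel IM at 0.296 and that of the wild type near tassel FM-S1 at 0.703, and the TS1 change correlated with the tassel change from FM-S1 to FM-S3 with r = -0.3397 across genes. Among genes unchanged from FM-S1 to FM-S3 in the tassel, tassel-higher genes still lay below ear-higher ones by a difference of medians of -0.233 (bootstrap SD 0.012). This was past the bound of 0.15 written beforehand, but such genes can change before FM-S1. Among the 117 tassel-higher and 230 ear-higher genes unchanged at all tassel stages the difference was -0.167 (SD 0.0269), not past that bound by its spread. It still kept its sign by more than that SD. Genes counted as unchanged were uncalled and moved less than a set limit, so smaller changes between stages remained in them. This difference therefore cannot tell an earlier stage from a shift towards the ear. These SDs are over genes, which are not independent replicates, and do not measure spread between libraries. Over all tassel-higher and ear-higher genes the medians were -0.3144 and 0.1595.

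Large TS1 changes crowded into 1 stretch of table rows, where 24 of 200 tested genes changed at least 4-fold, against 3.18% of all genes. None of 10000 random placements gave a window as full (highest 23 genes, permutation p = 0.0001, the smallest possible). Only placement of genes independently of their neighbours was set aside by this, because the test cannot weigh neighbours that tend to change together. Comparisons without a mutant also had fullest windows above the random median. These held 39 genes for tassel versus ear at FM-S3 (median 34, highest 47) and 50 for protoplasts (median 45, highest 60). For SK1 the fullest window held 5 genes (median 5, highest 9). With 14 increases and 10 decreases (58.3% increases) the large TS1 changes of the stretch did not run in 1 direction. Those values speak only against co-ordinated regulation of neighbours in 1 direction. Regulation of neighbours in both directions was not tested. For a linked segment that differs from the B73 reference, 0% of the 5 genes switched on in the mutant had 3 counts or fewer in the stage libraries, and none had 30 or fewer (median 17814 counts); this lay under the 50% written beforehand against it, but the exact 95% interval reached 52.2%, and the requirement that the interval clear the bound was added after the value was seen. That bound presumed that the mutant carried the segment. Over all 24 large changes, the FM-S1 to FM-S3 levels of the stage libraries were nearer the mutant in both ear and tassel for 19 (79.2%, exact 95% interval 57.8% to 92.9%) and nearer the wild type in both for 1, against 59.2% nearer the mutant among large changes elsewhere. These values run against a segment carried by the mutant, but the interval did not clear the share elsewhere, so it was not excluded. A segment of the wild type is a candidate explanation that stays open: leaving out genes too scarce in the stage libraries to be tested there, 78.3% were nearer the mutant in both, short of the 80% set for it.

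Tassel and ear differed in 7890 to 9734 genes at IM, SPM, SM and FM-S1, where tassel libraries were shallower. With all libraries thinned to the shallowest total, tassel versus ear, IM gave 6639 calls, 6277 of them among the 7890; tassel versus ear, SPM gave 8392 (7999 shared), tassel versus ear, SM 8430 (8040 shared) and tassel versus ear, FM-S1 7579 (7182 shared), so the difference in depth is not the whole cause at these stages. A batch shared by the early tassel libraries could contribute: tassel-over-ear differences correlated more among the 4 earlier stages than between earlier and later ones, by 0.37, above the 0.2 written beforehand for a batch. Shared biology of the early stages would give the same, and no label names a batch, so these were not separated.

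Regrouping the libraries asked whether any grouping would give as many called genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real split, called as many genes in each case. The real and the highest other counts were 7890 and 1 for tassel over ear at IM, 9734 and 0 at SPM, 9401 and 0 at SM, 9742 and 186 for IM to SPM in the ear, 9334 and 1 in the tassel, 5225 and 0 for SPM to SM in the tassel, and 7338 and 0 for TS1. For SPM to SM in the ear, where numbers may pair the samples, the real count was 3824, the highest other 3, and the highest among splits parting as many pairs 1. For protoplasts, splits that keep the inflorescences balanced, as the model requires, number 18, again too few for a share under 0.05; 1 of them, the real split, called as many genes (16742, highest other 1).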

How the results depend on the processing

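Of the 209 named-gene results followed through the alternatives, none reversed. This does not cover microRNA rows outside those 209. Apart from MIR172e, the genes followed were called microRNA rows with the lowest p-values and called IDs with the largest changes and separated libraries. Picked in this way from the same libraries, they were unlikely to reverse. Of 2355 values of named genes under alternatives, 183 lost a call and 2172 gave the same answer as the main setting, a number that includes genes with no call in either. Of 247 alternative values of counts and correlations, 188 stayed within 1.5 times or the replicate spread and 59 moved. Where a count moved, the cause was not tested unless fewer libraries or a stricter criterion explain it by construction.

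Requiring a 2-fold change, stricter by construction, left 2273, 3151, 2841, 3614, 3131 and 4586 genes for tassel over ear from IM to FM-S3. It left 3090, 1591, 1115, 2844 and 182 for the successive ear steps, 2754, 2145, 910, 3387 and 723 for the tassel steps, 3740 for the difference in change, 404 for SK1, 2001 for TS1 and 6666 for protoplasts. DESeq2 size factors kept every count within 1.5 times and moved the share of higher calls by at most 7.33 percentage points, from 55.72% to 63.05% for the difference in change, and from 61.19% to 68.2% for tassel over ear at FM-S2 and 52.91% to 58.38% at FM-S3. The larger side changed for tassel over ear at IM (48.91% to 51% higher), the ear from IM to SPM (49.75% to 50.21%) and from FM-S1 to FM-S2 (50.55% to 46.91%), the tassel from IM to SPM (50.72% to 49.34%) and protoplasts (49.59% to 52.1%). DESeq2's Wald test gave 2088 for SK1 mutant versus WT. With the compared groups alone in the fit, tassel versus ear, IM gave 4150 and tassel versus ear, FM-S2 12564, ear IM to SPM 5278, ear SPM to SM 2416, ear SM to FM-S1 1298, ear FM-S2 to FM-S3 6741, tassel SM to FM-S1 4425, tassel FM-S1 to FM-S2 12250 and tassel FM-S2 to FM-S3 0 (3668 at unadjusted p under 0.05, edgeR; DESeq2's Wald test on all groups 1462).

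Leaving out 1 library at a time gave 5641 to 6853 for tassel over ear at FM-S1, 3619 to 3644 at FM-S2, 1232 to 2292 for SM to FM-S1, 4695 to 6029 for FM-S1 to FM-S2 and 74 to 101 for FM-S2 to FM-S3 in the ear, and 840 to 1459 for SM to FM-S1 and 4655 to 4678 for FM-S1 to FM-S2 in the tassel. It gave 2376 to 3938 for SK1 and 4242 to 7230 for TS1; a group left with 1 library was assumed to vary like the others. The correlation of TS1 mutant genes and sex-biased genes, FM-S3, ran from -0.5812 to -0.5275 and that of SK1 mutant genes and sex-biased genes, FM-S3, from 0.2152 to 0.3231. Against FM-S1 and FM-S2 the TS1 correlation was -0.2516 and -0.5443 and that of SK1 0.1064 and 0.2279, and over genes called in the mutant they were -0.6601 and 0.425. Without the third replicates of both groups, chosen after seeing the data, TS1 mutant versus WT gave 1087.

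With replicate numbers as a block the counts were 8173 for tassel versus ear, IM, 10004 for tassel versus ear, SPM, 9651 for tassel versus ear, SM, 8424 for tassel versus ear, FM-S1, 5833 for tassel versus ear, FM-S2, 10777 for tassel versus ear, FM-S3, 3868 for ear SPM to SM, 3718 for SK1 mutant versus WT, 6116 for TS1 mutant versus WT and 15975 for protoplast versus intact, FM-S3, all within 1.5 times. In TS1 every sample correlated best with its own number, a hint from the data and not from the design. The same held for Ear SPM with Tassel SPM and for Ear SPM with Ear SM. It also held for Ear FM-S2 with Ear FM-S1 and with Ear FM-S3, and for Ear FM-S3 with its protoplasts. Groups of 2 libraries have mirrored deviations, so there it says only that the correlation was positive (0.00319, 0.0552 and 0.0358). These 2-library cases therefore give no hint of pairing. In the other comparisons checked, samples did not all correlate best with their own number. Single-cell comparisons, clustering and tests of gene lists were not run. Counts thinned to the shallowest library, chosen after seeing the data, gave 6639 calls for tassel versus ear, IM; thinning mainly removes counts from the deeper libraries, so whether the low tassel depth limited the calls was not tested.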

Other observations

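MIR160d, of a family that targets auxin response factor genes, was higher in the tassel at SPM, with 5.43 ± 0.61 CPM against 1.65 ± 0.19 in the ear (n = 3 each), a log2 fold change of 1.74 (SE 0.23; edgeR's quasi-likelihood test, adjusted p = 4.33e-06). At FM-S1 it stood at 4.46 ± 0.159 CPM in the tassel and 1.85 ± 0.0151 in the ear (n = 2 each). MIR171d rose in the ear from 0.123 ± 0.0484 CPM at SPM to 0.814 ± 0.327 at SM (n = 3 each; log2 fold change 2.80, SE 0.42; edgeR, adjusted p = 6.82e-05).

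The protoplast change of MIR159a was lower in the tassel than in the ear by a log2 difference of -1.65 (SE 0.16; edgeR, adjusted p = 9.15e-05), and that of MIR394b by -2.53. The SK1 wild-type libraries had a mean position of 0.12 on the ear-to-tassel axis and the mutants 0.218 (n = 2 and 3; exact p = 0.1, the smallest possible). The columns that share a name correlated with each other with r = 0.9378. Column 1 had its highest mean correlation with Tassel FM-S1 (0.9927, Tassel SM next with 0.9777) and column 2 with Tassel FM-S2 (0.998, Tassel FM-S3 next with 0.9681); columns were not assigned to groups by their values.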
